A study of Homo sapiens with 2 samples.

How the data were processed

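Total RNA was extracted with Trizol from untreated cultures of 2 human prostate cancer cell lines, amplified with the Ambion WT Expression Kit, fragmented, biotinylated with the Affymetrix WT Terminal Labeling Kit and hybridised to Affymetrix whole-transcript arrays, per the labels' protocols. C4-2B is a castration-resistant line derived from LNCaP and is docetaxel sensitive per the labels. TaxR is docetaxel resistant and was obtained from C4-2B by prolonged culture with docetaxel, per the series' design text. Each line has 1 array in the data used here. No p-value, standard error or other measure of the spread between cultures can therefore be given. The number of arrays limits the precision of every value.

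The deposited values are on a log scale, taken here as log2, and were centred by the authors, or by their software, for each probe set on a baseline that is not part of the table used here. The column medians were 0.01 for C4-2B and -0.0043 for TaxR, and both columns held values of both signs. The software, the summarisation, the normalisation between arrays and the centring are not given in the sources used here. The log base is not stated either. Base 10 was ruled out because the largest difference, 6.49, exceeds the log10 range of 4.82 that a 16-bit scanner allows. Base 2 was taken because it is the usual scale for such arrays. The rounding steps left in the values showed no sign of levels under 4 before centring, and no upper end was read from them. They do not rule out the natural logarithm, whose range on such a scanner ends at 11.1. Every fold given here, and the name log2, rests on base 2. With base e a difference of 1 would be 2.72-fold and the largest difference 659-fold, while differences, ranks and percentiles would stay as they are. Because the baseline cancels in the difference between the arrays, only TaxR minus C4-2B is interpreted, and no absolute level is given. Centring also makes the columns run against each other (correlation -0.398 across probe sets, which are not independent replicates).

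Of 28869 probe sets, 19310 paired with 1 gene symbol in the platform annotation, 1752 with several and 7807 with none. Symbols were updated through gene identifiers, and 99.8% of the identifiers were found in the reference gene table (assembly GRCh38.p14, used only for names and for which genes neighbour each other, since no build is named for the array), which left 31 genes with the annotation's own name. Probe sets with several genes or none were kept out of the gene table. The difference of a gene was the mean over its probe sets, which gave 18377 genes, 17692 of them with 1 probe set. Over the 532 genes with exactly 2 probe sets, the SD of the difference between both was 0.14, and the pooled SD of a probe set around its gene was 0.09 on the log2 scale. This spread covers probe and hybridisation noise within these arrays only.

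A filter on level, random lists matched in bins of mean level, the choice of the brightest probe set of a gene, quantile and loess scaling, and a floor under low levels had been fixed before the data were examined. None of them can be run on centred values. In their place no filter on level was applied, probe sets of a gene were averaged, and random lists were matched on 2 classes of level that the rounding steps give. A value on an odd multiple of the finer step shows that the array's level or the baseline was under 8. This held for 6923 genes, called dim here, and was not shown for 11454. In a check on known classes, 0% of the ribosomal protein list and 77.2% of the olfactory receptor genes were shown dim. A part of the dim genes escapes this rule by chance.

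Genes at least 2-fold apart were counted in each direction. For 31 gene lists fixed before the data were examined (690 of their 781 genes were measured, and some genes stand in several lists), the median difference was set among the medians of 10000 random lists of the same size and level classes, and a list was said to stand apart when its median lay outside their central 95%. By chance 1.55 of the 31 lists would. Percentiles describe these 2 arrays only. A second matching also used the number of neighbouring genes within 500 kb and gene length, because the differences varied with both: the median difference was 0.00 in the fifth of genes with the fewest neighbours and -0.05 in the fifth with the most. Medians over 11 neighbouring measured genes were taken along each chromosome. The text names the 12 genes with the largest positive and the 12 with the largest negative difference (small RNA, long non-coding, olfactory, open reading frame and Y-linked symbols and XIST left out), in each list described up to 2 members with the largest positive and 2 with the largest negative difference, the members of the ABCB1 window, and 12 genes fixed in advance, of which 10 were measured and the others were not analysed here. A gene named outside this rule is said to be so. On data simulated for 18377 genes, 48 of 50 genes moved by 1.2 and 49 of 50 moved by -1.2 passed the 2-fold threshold, and 0 of 18177 unmoved genes did. Of 100 simulated lists of 25 genes, 3 stood apart with no shift, 42 with a shift of 0.05 and 100 with a shift of 0.1. The simulated genes were independent, with normal noise whose spread was taken from the quartiles of the real differences. These runs check the code and give no rate at which real genes or lists would pass without a change. Alternatives covered median centring, genes with 1 probe set, all probe sets, other fold thresholds, the matching, leaving out the largest member, dim genes and the window width. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.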

Results

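Gene expression was measured in 2 prostate cancer cell lines, the docetaxel-sensitive line C4-2B and the docetaxel-resistant line TaxR that was selected from it, with 1 array per line and no drug in the medium. Docetaxel is a taxane, which stabilises microtubules and blocks mitosis. The comparison asks which genes differ between the resistant line and its parent. All values are differences of log2 signal, TaxR minus C4-2B, for 18377 genes. The data used here held no replicate array, so the values describe these arrays and no difference could be tested against the spread between cultures.

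ABCB1, which encodes the drug efflux pump P-glycoprotein, differed more than any other gene: it was higher in TaxR by 6.49 on the log2 scale, or 89.9-fold, where this and every other fold takes the unstated log base as 2. KRT20, an intermediate filament keratin, followed with 2.99 (7.96-fold), and RUNDC3B, the gene next to ABCB1, with 2.74 (6.69-fold). The complement receptor gene CR1 was higher by 1.83, the adhesion gene NECTIN3 by 1.24, the secreted synaptic protein gene CBLN2 by 1.204 and RND3 by 1.09. PEG10, an imprinted gene derived from a retrotransposon, was the only gene at least 2-fold lower in TaxR (-1.55). The non-coding gene LINC00221 (1.91) completes the 8 genes at least 2-fold higher and is named after its value was seen. Most genes differed little: the median difference was -0.02, and the 5th and 95th percentiles were -0.23 and 0.19. At 1.5-fold the counts were 32 higher and 21 lower. KRT20, CR1, NECTIN3, LINC00221 and PEG10 were shown dim by the rounding of their values, and without dim genes 4 genes were at least 2-fold higher and 0 lower.

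**Figure D1:**
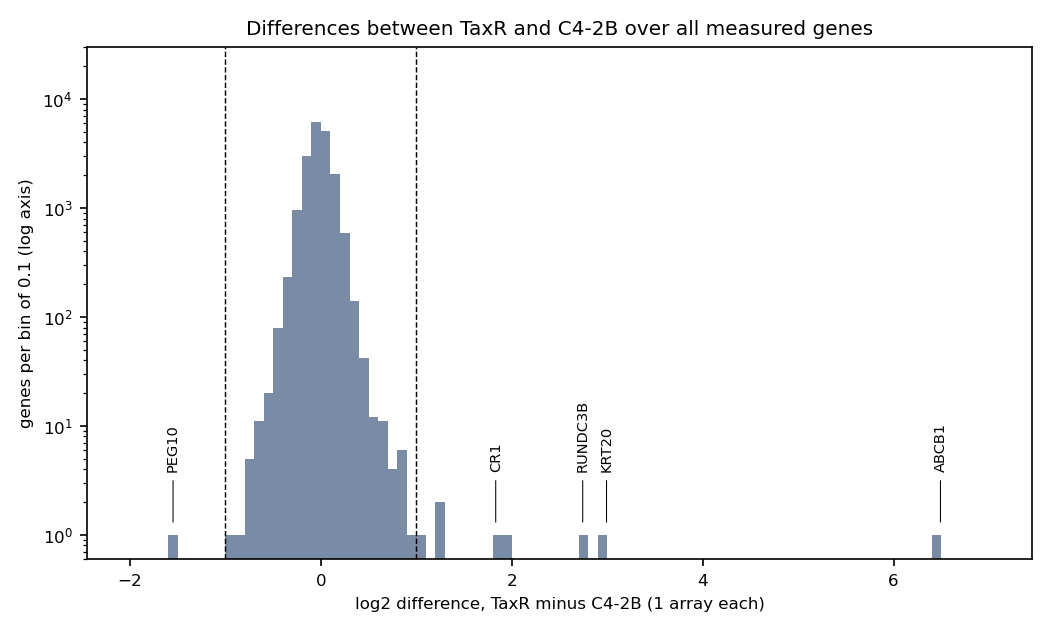
Number of genes (log axis) by log2 difference between the TaxR and the C4-2B array, in bins of 0.1, with dashed lines at 2-fold. ABCB1 stands at 6.49, far from KRT20 at 2.99 and RUNDC3B at 2.74, and PEG10 is the only gene beyond the left line.

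Just under 2-fold, BRINP1 was higher by 0.996, LRRN1 by 0.89, the insulin-like growth factor binding protein gene IGFBP3 by 0.87, the protocadherin gene PCDH20 by 0.86 and PLPPR1 by 0.86. On the lower side, the ephrin receptor gene EPHA3 stood at -0.996, the mannosidase gene MAN1A1 at -0.74, the actin-bundling gene LCP1 at -0.72, S100P at -0.72 and the androgen-induced channel gene TRPM8 at -0.71. BMP7 followed at -0.69, TFPI at -0.67, CYP4F8 at -0.67, TMEM45B at -0.66, APOBEC3F at -0.64 and the stress-induced growth factor gene GDF15 at -0.64. Each of these rests on 1 probe set. For comparison, the SD of the difference between 2 probe sets of the same gene was 0.14.

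The large difference of ABCB1 was not shared by other transporters. Among 28 measured ABC transporter genes, ABCB1 was the only member at least 1.2-fold higher, and 14 members lay above and 14 below the median of all genes. ABCG4 (0.24) came next after ABCB1, and ABCA3 (-0.31) and ABCA2 (-0.26) were the lowest. ABCG2, another efflux pump linked to drug resistance, differed by 0.13, ABCC1 by -0.22 and ABCB4, the closest relative and direct neighbour of ABCB1, by 0.02. Of the 28 genes, 14 were shown dim, among them ABCG4, ABCG2 and ABCB4, and a floor under low levels could shrink their differences. The list median was -0.03, at percentile 30.4 of random lists. Without dim genes its percentile was 0.63. Among 17 solute carriers that transport drugs, SLC15A2 (0.45) and SLC22A7 (0.05) were the highest, and the organic anion transporter genes SLCO3A1 (-0.64) and SLCO4A1 (-0.50) the lowest, with the list median at percentile 24.9.

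Several of the nearest neighbours of ABCB1 on chromosome 7 were moderately higher in TaxR. In the window of 11 measured genes centred on ABCB1, the median was 0.20, and 11 of 18105 windows, or 0.0608%, had a median at least as high, overlapping windows and this window included. Besides ABCB1 and RUNDC3B, the window held CROT (0.30), DBF4 (0.28), SLC25A40 (0.21), DMTF1 (0.20), ADAM22 (0.11), TP53TG1 (0.10), ABCB4 (0.02), SRI (0.02) and TMEM243 (-0.07). Beyond SRI, STEAP4 was lower (-0.31). Without ABCB1 and RUNDC3B the window median was 0.10, which 166 windows reached, and without ABCB1 alone 119 windows reached its median. In a window of 21 genes it was 0.022, a value that 2757 windows reached. In the list of 21 genes near ABCB1 fixed in advance, which leaves out ABCB1, 3 genes were at least 1.2-fold higher and 1 was as much lower (STEAP4, with CLDN12 next at -0.19), with the median at percentile 90.8. Without dim genes that percentile was 99.9, and with matching on level class, neighbour number and gene length it was 69.6.

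**Figure D2:**
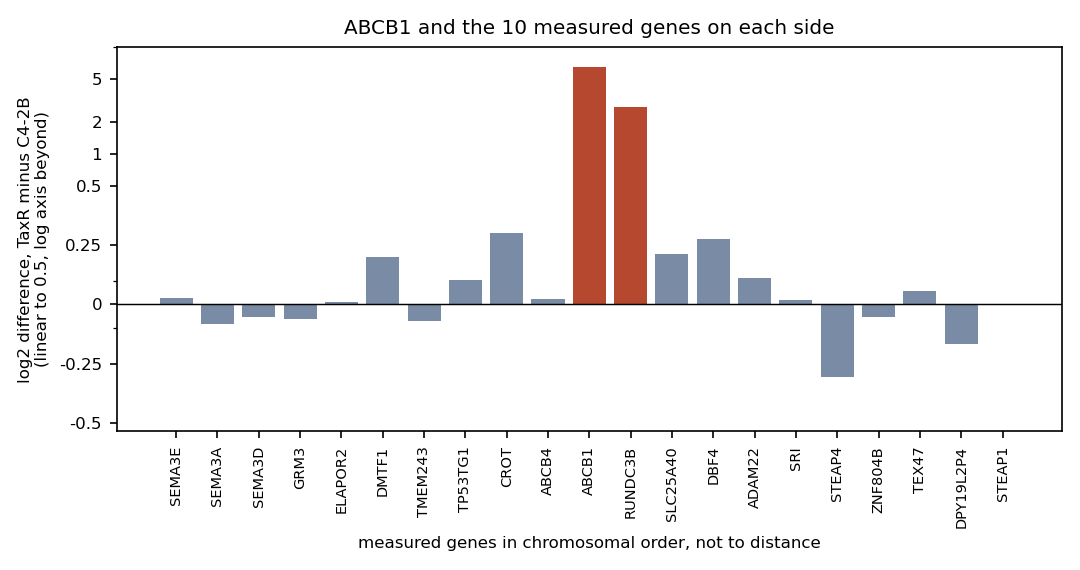
Log2 difference between TaxR and C4-2B for ABCB1 and the 10 measured genes on each side, in chromosomal order and not drawn to distance. The axis is linear up to 0.5 and logarithmic beyond, and ABCB1 (6.49) and RUNDC3B (2.74) are in red, while CROT at 0.30 is the highest of the others.

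The measured genes of the taxane target differed little. Of 20 listed tubulin genes, 18 were measured. TUBB3, a gene fixed in advance to be named, was not measured, so its difference is unknown here. The 18 measured genes ranged from -0.21 (TUBE1) to 0.07 (TUBA1A), with TUBB2A at -0.10 and TUBA3C at 0.06. None reached 1.2-fold, and their median lay at percentile 56.6 of random lists. Among 37 microtubule-associated protein genes, 1 was at least 1.2-fold lower (MAP7D1, -0.30) and none was as much higher. MAP1S was at -0.24, CLIP2 at 0.23 and FIGN, a severing enzyme, at 0.23, and the list stood at percentile 47.1.

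Cell cycle lists stood apart on opposite sides. The mitotic spindle and checkpoint list stood apart on the higher side, with a median of 0.04 over 34 genes at percentile 99.7. Of these genes, 21 lay above and 13 below the median of all genes, with 2 at least 1.2-fold higher and 1 lower. The kinesin gene CENPE (0.39) and the kinetochore gene CENPF (0.31) were the highest, and the separase gene ESPL1 (-0.26) and the kinase gene AURKB (-0.21) the lowest. The DNA replication list stood apart on the lower side, with a median of -0.09 over 31 genes at percentile 1.13, and 24 of them lay below the median of all genes. The licensing factor gene CDT1 (-0.28) and the origin recognition gene ORC1 (-0.23) were the lowest, and CCNE2 (0.19) and RFC3 (0.11) the highest.

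The luminal and androgen receptor target lists stood apart on the lower side, mostly through small differences. The luminal prostate epithelium list had the lowest median, -0.15 over 20 genes at percentile 0.01, and 16 of its members lay below the median of all genes, 2 of them at least 1.2-fold lower. AGR2 (-0.44) and the tight junction gene CLDN3 (-0.35) were the lowest, and TJP1 (0.06) and MUC1 (0.04) the highest. The androgen receptor targets had a median of -0.11 over 23 genes at percentile 0.18. TRPM8 (-0.71) and HERC3 (-0.41) were the lowest and EAF2 (0.27) and MPHOSPH9 (0.13) the highest, with 6 members at least 1.2-fold lower and 1 higher. KLK3, which encodes prostate-specific antigen and is a target often measured, differed by -0.05. CDH1, an epithelial adhesion gene in the luminal list, differed by -0.03. The steroid synthesis and conversion list was at percentile 94.95, inside the central range, with 17 of 24 genes above the median of all genes, HSD17B11 at 0.35, AKR1C2 at 0.33, CYP11A1 at -0.18 and AKR1C4 at -0.11. AKR1C3, which makes testosterone from androstenedione, differed by -0.03 and was among the 15 genes of this list shown dim.

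No list of markers of other cell states stood apart in the main run. The mesenchymal list was at percentile 83.5 (98.9 without dim genes), with 20 of 28 genes above the median of all genes. VIM, the mesenchymal intermediate filament gene, was at 0.39, SNAI2 at 0.36, LOX at -0.50 and COL6A1 at -0.12. In the basal epithelium list 10 of 11 genes lay above the median of all genes, from LAMB3 (-0.09) to KRT14 (0.15) with S100A2 at 0.00 and CD44 at 0.09, at percentile 86.5. The neuroendocrine list was at percentile 32.8, although the vesicle gene SYT4 stood at 0.85 and SYP at 0.23, against DDC at -0.60 and ENO2 at -0.27. The stem cell, Notch and Hedgehog list was at percentile 23.6, with GLI3 at 0.33, PTCH1 at 0.13, KLF4 at -0.41 and SOX9 at -0.24. The fibroblast, endothelial and blood markers were at percentile 30.8, between MYH7 (-0.15) and PDGFRB (0.20), with ALB at -0.10 and GFAP at 0.13.

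Among survival and signalling genes, the growth factor receptors and ligands stood apart on the lower side, with a median of -0.07 over 28 genes at percentile 1.67. FGFR3 (-0.45) and IGF1R (-0.34) were the lowest, and PDGFRB (0.20) and PDGFC (0.08) the highest. Without dim genes the percentile was 2.99, inside the central range. Protective apoptosis regulators were at percentile 37.8, with BAG1 at -0.23, BCL2L1 at -0.18, BIRC7 at 0.13 and BIRC2 at 0.09. BCL2 itself, shown dim, differed by 0.04. Promoting apoptosis regulators were at percentile 7.06, with BIK at -0.31, BAK1 at -0.19, CYCS at 0.11 and CASP8 at 0.09. The p53 targets were at percentile 71.9, with GDF15 at -0.64, SESN2 at -0.38, TP53INP1 at 0.21 and RRM2B at 0.13. CLU, a secreted chaperone gene, differed by -0.07. Integrins and laminins were at percentile 13.0, with ITGA5 at -0.34, ITGB5 at -0.22, LAMB1 at 0.34 and ITGB1 at 0.16.

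Stress and metabolic lists varied. The heat shock and chaperone list lay just above the central range, with a median of 0.03 over 20 genes at percentile 97.6, which fell inside the range under several settings. DNAJB4 (0.54) and DNAJA1 (0.22) were the highest, CRYAB (-0.43) and HSF1 (-0.25) the lowest. The unfolded protein and integrated stress response list held 5 members at least 1.2-fold higher and 4 lower, at percentile 43.5, with DNAJC3 at 0.48, HSP90B1 at 0.32, CHAC1 at -0.44 and SESN2 at -0.38. Cholesterol synthesis was at percentile 95.6, with SC5D at 0.36, HMGCS1 at 0.34, TM7SF2 at -0.37 and PMVK at -0.22, and at percentile 99.1 without TM7SF2, the member with the largest difference in size. Hypoxia and glycolysis genes were at percentile 38.0, with 5 of 27 at least 1.2-fold lower, among them SLC2A1 (-0.37) and ALDOC (-0.32), while SLC2A3 (0.17) and ERO1A (0.05) were the highest. Glutathione and NRF2 targets were at percentile 86.3, with GSTA1 at 0.27, NFE2L2 at 0.15, GPX2 at -0.33 and GSTT1 at -0.27. Cytochrome P450 and taxane metabolism genes were at percentile 51.4, with CYP1A1 at 0.29, AHR at 0.21, POR at -0.13 and CYP2U1 at -0.12.

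Immune and reference lists lay inside the central range. Interferon-stimulated genes were at percentile 29.1, with BST2 at -0.42, IFI35 at -0.26, IFIT3 at 0.17 and OASL at 0.17. Antigen presentation genes were at percentile 26.2, with TAP2 at -0.23, TAP1 at -0.22, PSMB8 at 0.20 and HLA-DPB1 at 0.09. The NF-kappaB targets and cytokines were at percentile 69.5, and at 1.71 without dim genes, with NFKB2 at -0.49, CCL2 at -0.24, LTB at 0.33 and CXCL10 at 0.26. Ribosomal protein genes were at percentile 50.2, between RPLP1 (-0.25) and RPL18 (0.04), with RPS19 at -0.21 and RPL11 at 0.02. Housekeeping genes were at percentile 76.4, with POLR2A at -0.42, GUSB at -0.22, TOP1 at 0.23 and TBP at 0.17. In all, 6 of the 31 lists stood apart from random lists, 2 on the higher and 4 on the lower side.

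**Figure D3:**
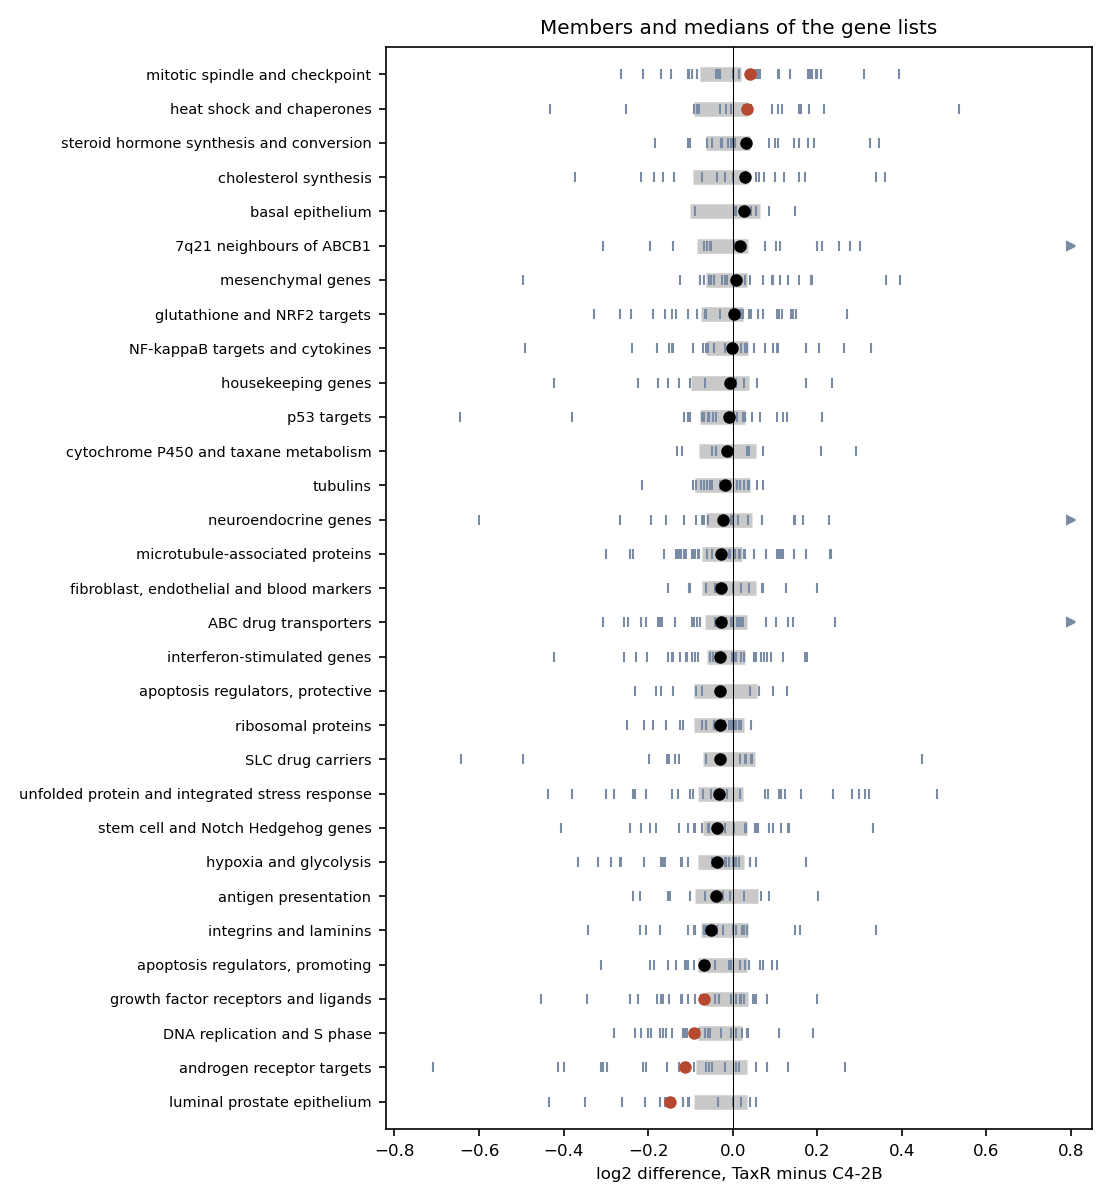
Log2 difference between TaxR and C4-2B for the members (ticks) and the median (dot) of each of the 31 gene lists, with the central 95% of medians of random lists as grey bars. Red dots mark the 6 medians outside the grey bar, and arrowheads at the right edge stand for members beyond 0.8.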

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

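The tests of a gained segment, of the number of lists, of the baseline and of a floor under low levels were chosen after the result was seen.

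Probe sets that pair with several genes or none, which the comparison of genes did not use, held large differences in both directions. At least 2-fold higher in TaxR were 4 of these 9559 probe sets, each listing several UGT2B genes, with 1.31 as the highest difference and 1.15 as the lowest. Some enzymes of the UGT2B family, not all, inactivate androgens by glucuronidation. Another 4 were at least 2-fold lower, of which all but a probe set without a listed gene (-1.08) list the same FCGR1 genes (-1.09 to -1.32). Which member gave the signal cannot be read from probe sets that match several genes. Among members with a probe set of their own, named after their values were seen, UGT2B28 differed by 0.65, UGT2B17 by 0.18 and UGT2B7 by 0.04.

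The pattern of most interest is the block around ABCB1. A gain of a segment that raises 4 measured genes on each side by several log2 units is argued against by their median of 0.11 (SD 0.13 over 8 genes). These flanking genes still stood at percentile 98.3 of random lists matched on level, neighbour number and gene length. They are members of the window whose high median gave the pattern, and random lists draw scattered genes. Their percentile therefore partly restates the pattern and cannot decide whether the trend with those properties accounts for it. The wider list of 21 neighbours fixed in advance stood at percentile 69.6 with the same matching, inside the central range. ABCB1 and RUNDC3B overlap in the reference assembly, and across 1703 other overlapping pairs the differences correlated at 0.0808 (standard error 0.0243 if pairs were independent), against 0.0927 in 14297 neighbouring pairs without overlap, which leaves signal shared between this pair open. A smaller copy gain, or activation of a stretch that holds both genes, may underlie the block, and neither can be told from expression on 1 array per line.

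The luminal, androgen receptor target, replication and spindle lists form another pattern. With matching on the 3 properties their percentiles were 0.02, 0.06, 0.27 and 99.3. The trend across the matched classes of level, neighbour number and gene length is therefore not their whole cause. Level entered as 2 classes only, and a part of the dim genes escapes that rule. A trend with level inside a class was thus not controlled. Whether the number of lists looked at accounts for them stays open: 6 lists stood apart, heat shock among them only just. Genes of a list may vary together, which was not measured here, so the 1.55 that chance gives for independent genes may be too low a bound. Culture density, passage and growth rate may differ between any pair of dishes and cannot be separated from resistance here. Lower luminal and androgen receptor target expression in TaxR is therefore a hypothesis drawn from these same values (percentiles 0.02 and 0.06). Replicate cultures are needed to test it.

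In the centred table, values of both arrays that sum to 0 within 2e-06 were found for 15.4% of probe sets, near the 16.67% that a median over 4 arrays gives and far from the 6.667% of 6 arrays, so the baseline may be the median over these and 2 further arrays, which were not analysed here. That share rests on the tolerance, since 7.81% of probe sets summed to exactly 0, while it was 15.4% at 1e-06 and 15.6% at 0.0001. Among the 17 probe sets at least 2-fold apart the median ratio of the sum to the difference was 0.0786, which says nothing of the further arrays, since choosing a large difference favours a small ratio. Of 56652 values of at least 0.001 in size, 0 lay only on the rounding step that levels under 4 would give (smaller values are written with too few digits to read), which fits a floor at 4, such as adding 16 to the signal if the base is 2. Such a floor would shrink the differences of dim genes such as KRT20, CR1 and PEG10, and of ABCB1 if its C4-2B signal, -3.19 from the baseline, lay near the floor, and their folds may then be understated.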

How the results depend on the processing

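The 1.2-fold threshold, the count over all probe sets, the matching on 3 properties, the runs without dim genes and the window without ABCB1 and RUNDC3B were chosen after the data were seen. No list that stood apart changed side. The medians of 5 other lists changed sign under some settings (tubulins, cytochrome P450, NF-kappaB targets, p53 targets and housekeeping genes), each within 0.02 of 0 in the main run. Genes at least 2-fold higher numbered 8 and lower 1; the counts were 32 and 21 at 1.5-fold, 3 and 0 at 4-fold, 352 and 570 at 1.2-fold, and 4 and 0 without dim genes, and 12 and 5 over all probe sets. Of 155 runs of the lists under other settings, 144 stayed on their side of the central range, median centring not counted since it cannot move a percentile. Without dim genes, 4 lists moved outside it: ABC transporters (percentile 0.63), neighbours of ABCB1 (99.9), mesenchymal genes (98.9) and NF-kappaB targets (1.71), and growth factor receptors moved inside (2.99). Cholesterol synthesis moved outside without the member of largest size, TM7SF2 at -0.37 (99.1), and with matching on 3 properties (97.6). Heat shock moved inside with no matching (95.7), without DNAJB4 (96.9), with 3 properties (97.4) and without dim genes (97.3). The ABCB1 window's median was reached by 2 windows at a width of 7 genes, 2757 at 21 genes (median 0.022), 119 without ABCB1, and 166 without ABCB1 and RUNDC3B (median 0.10). The cause of these shifts was not tested. The median over probe sets was -0.015, so median centring raised every difference slightly, put BRINP1 at 1.01 and turns the sign only of differences between -0.015 and 0. Not run, because the values are centred: quantile and loess scaling, filters and floors on level, and matching in bins of level. Signal over background is unknown for single genes, and no array can be left out of a comparison of 1 with 1.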

Other observations

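The split of the stress response list into a higher and a lower part was noticed after its values were seen. The further lists used to test it were chosen then, and their bounds were written before the values of their genes were looked at. Genes named in this part were chosen after their values were seen, and symbol families were grouped only after the data were seen.

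Within the unfolded protein and integrated stress response list, several genes for folding in the endoplasmic reticulum were higher in TaxR and several genes induced by the transcription factor ATF4 were lower, though no sublist had been fixed and 5 of 28 members reached 1.2-fold on the higher and 4 on the lower side. The chaperone genes DNAJC3 (0.48), HSP90B1 (0.32), DNAJB11 (0.31), HSPA5 (0.30), PDIA4 (0.28) and PDIA6 (0.24) stood on the higher side, CANX (0.11) and CALR (0.08) closer to 0, and EDEM1 (-0.13) and XBP1 (-0.01) not higher. On the lower side were CHAC1 (-0.44), SESN2 (-0.38), DDIT4 (-0.30), PCK2 (-0.28), ASNS (-0.24), CTH (-0.23) and TRIB3 (-0.21), with ATF4 itself (-0.09), PSAT1 (-0.07) and PHGDH (-0.05) closer to 0, while DDIT3 (0.16) and ATF3 (0.12), also induced in this response, were not lower. A further list of 30 folding and translocation genes outside the first list had a median of 0.05 over 26 measured genes, at percentile 99.2 of random lists matched on 3 properties, with MANF (0.27), SEC63 (0.24), ERP44 (0.24) and CRELD2 (0.22) the highest and KDELR3 (-0.34) the lowest. A further list of 30 ATF4 targets had a median of -0.08 over 29 measured genes, at percentile 1.96, with SLC7A5 (-0.36), SLC7A1 (-0.22) and ALDH1L2 (-0.19) the lowest and SLC38A2 (0.13) the highest. That these gene groups differ between the lines is a hypothesis from 2 arrays, and what it means for the cells was not measured. Medium exhaustion or cell density at harvest could give the same difference.

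Genes were also grouped by a shared symbol start into 244 families, of which 12 lay above and 13 below the central 95% of random lists. For independent genes chance gives 12.2 on both sides together. Among small RNAs, the 75 SNORD genes had a median of -0.13, the 60 SNORA genes of -0.11, the 20 SNORD116 genes of -0.17, the 15 RNU genes of -0.16 and the 16 SCARNA genes of -0.09, all below that range, though SCARNA (percentile 1.45) lay inside it with matching on 3 properties (3.3), and windows of SNORD116 genes had the lowest median on any chromosome, -0.24. The 20 SNORD115 genes (-0.01, percentile 47.9) and the 179 MIR genes (-0.01, percentile 52.9) lay inside it. Highest in median were the 14 genes whose symbols begin with HSP followed by digits, all HSP90 genes or their copies, at 0.18, with 12 of them above the median of all genes. Probe sets of near-identical copies can share signal, so these are not independent. Other families on the higher side included 314 of 493 ZNF genes, 48 of 67 KRTAP genes, 34 of 44 collagen genes, 30 of 37 CEP genes and 18 of 22 FGF genes above the median of all genes. On the lower side, 14 of 22 TSPAN genes and 15 of 23 claudin genes lay below it. So did 7 of 10 endoplasmic reticulum membrane complex (EMC) genes, whose median of -0.15 stood at percentile 0.6 (0.45 with matching on 3 properties). Their direction was opposite to that of the further folding and translocation list.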
